A study of Homo sapiens with 6 samples.

How the data were processed

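Poly(A) RNA sequencing compared 3 replicates of Cas9-expressing eHAP cells given guide RNAs against TFDP1 with 3 control replicates, described in the labels as biological replicates. RNA was prepared from a mixture of 500000 eHAP cells and 10000 Drosophila S2 cells per sample, the latter as a spike-in, and libraries made with a NEBNext Ultra II kit were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, featureCounts and edgeR and the builds hg38 and dm6, without versions or order; the settings of read counting, including strand, are not given in the sources used here.

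The values analysed are those of the authors' deposited table of the comparison. Its log2 fold change and log2 CPM columns were made by the authors, with edgeR per the submitters' processing notes, and the reference level of the fold change is not given in the sources used here. The authors' p-value and FDR columns come from a likelihood ratio test, per the file headers. The likelihood ratio is a score per gene, as the authors deposited it, on 1 degree of freedom. How the authors scaled the libraries, by the human reads or by the spike-in, is not given in the sources used here. The 15794 rows all carry the hg38 prefix, and 9 p-values and 10 FDR values are listed at 0. The deposited FDR values were compared with the ranks of the p-values and imply an adjustment over about 18711 rows, 2917 more than the rows analysed. The levels range from 0.0922 to 5017 CPM and sum to 988179 CPM, which leaves 1.18% of the CPM scale outside these rows.

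Values per sample were not used here, so library depths are unknown, replicates were not compared, and the p-values are the authors' own. The design fixed before the data were examined therefore took its form for a table of comparisons: genes were called at the authors' FDR under 0.05 and split by the sign of the fold change, and no new test across samples was made. An approximate standard error of each log2 fold change, its absolute value divided by the square root of the likelihood ratio, gives the precision at each level. Its median was 0.89 at the 982 genes between -3 and -2 log2 CPM, 0.21 between 1 and 2, 0.085 between 4 and 5 and 0.042 between 8 and 9. A change at the lowest of these levels had to exceed about 3.37-fold to lie beyond 1.96 standard errors, and one at the highest about 1.06-fold.

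A total of 25 gene lists was fixed before the data were examined. Each was tested with cameraPR of limma 3.58.1 in R 4.3.3, which compares a list with all other genes, on signed z scores made from the authors' p-values, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A p listed at 0 was set to the smallest p above 0. A correlation estimated from the samples could not be used, since it needs values per sample. TFDP1 was left out of every list test. The share of each list among positive and among negative calls was tested with two-sided Fisher's exact tests, adjusted over lists and directions. Each list's median was also ranked among 10000 random lists of the same size, matched in 10 bins of level. The text names TFDP1, the 8 genes per direction with the largest change among called genes at or above the median level, the 3 members of each list with the smallest p (4 for the E2F family, replication and replication-dependent histone lists, and none where no member was called), and E2F family members, pocket proteins and E-type cyclins whatever their p. Gene models without a symbol were passed over, and 1 gene that the rule names is not reported here. Cells of other types were covered by marker lists for blood, fibroblast, epithelial and neuronal cells.

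Positions, lengths and GC content came from GENCODE 29 on GRCh38, matched by symbol for 14777 genes (93.6%), using the longest transcript of each gene. Chromosomes with at least 50 genes were compared by two-sided Fisher's exact tests of the genes above the overall median, adjusted over 23 chromosomes, and the median of each was given a 95% interval from 10000 bootstrap draws of its genes, not adjusted over chromosomes. The differences of medians were also tested against 10000 permutations of the genes over the chromosomes, two-sided. Trends of log2 fold change on log2 transcript length and then on GC content were removed by lowess with a span of 0.3 (statsmodels 0.14.6), and the residuals were divided by the approximate standard error for the repeated tests. Gene symbols that share a root of letters, with at least 10 members, gave 190 further groups for the list test. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9, under Python 3.11.15.

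The tests were tested on simulated statistics for the same genes. With 15794 genes, the list test recovered 5 of 5 shifted lists and called 0 of 18 others. Fisher's exact test recovered 5 of 5 and was run on the shifted lists only, with calls at an unadjusted p under 0.05. With 14777 genes and a shift of 0.15 on 1 chromosome, the chromosome test recovered it in 30 of 30 simulations and called 2 of 660 unshifted chromosomes. That shift exceeds the largest observed one, 0.12 on chromosome 13, so recovery at the observed sizes was not tested. The simulated values were drawn independently for each gene, without a GC trend or correlation between genes. These rates therefore check how the tests run and do not give their false call rates on the deposited values. Alternatives covered other thresholds, adjustments, level filters, centrings, list statistics and preset correlations, and, added after the data were seen, tests of single genes recomputed after re-centring, list tests re-centred on the ribosomal protein median, the removal of length and GC trends and of 34 abundant genes with extreme likelihood ratios.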

Results

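Polyadenylated RNA was sequenced from eHAP cells, an engineered haploid human line derived from HAP1, which is of chronic myeloid leukaemia origin. The cells expressed Cas9 and were transfected with a plasmid carrying guide RNAs and puromycin resistance, selected with puromycin from 24 to 72 h, and collected at 5 days. The 6 samples form 2 groups, 3 biological replicates with guides against TFDP1 and 3 control replicates. TFDP1 encodes DP1, the partner with which most E2F transcription factors bind DNA at promoters of cell cycle genes. The comparison asked which transcripts differ between cells targeted at TFDP1 and control cells. RNA was prepared from 500000 eHAP cells mixed with 10000 Drosophila S2 cells. The values are those of the authors' deposited table, which gives each of 15794 human genes a log2 fold change between the groups, a mean level in log2 CPM (read counts scaled to the library size), a likelihood ratio, a p-value and an adjusted p. Values per replicate were not used here, so the spread between replicates and the depth of each library are unknown. No fold change below therefore has a replicate error of its own, and the authors' p-values are the only measure of replicate variation. For 34 abundant genes with extreme likelihood ratios, described last, those p-values are uncertain.

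TFDP1 itself (chromosome 13, positions 113584721 to 113641470 of GRCh38, plus strand, protein coding, ENSG00000198176.12 in GENCODE 29) had a log2 fold change of 1.17, or 2.25-fold, at a mean level of 226 CPM in the authors' deposited table, with an adjusted p of 1.08e-283. The table does not state which group is the numerator of its fold changes. A small insertion or deletion made by Cas9 need not lower the transcript it hits, so the level of TFDP1 does not settle the direction either. Directions are accordingly given relative to TFDP1. A positive gene was higher in the group with more TFDP1 transcript, and a negative gene was lower in that group. Whether that group is the control or the knockout was left open.

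Among the 15794 genes, 6244 passed an adjusted p of 0.05 in the authors' deposited table, 39.5% of those tested. Of these, 2738 were positive and 3506 negative. The changes were mostly small, with a median of 1.26-fold and 4770 of the 6244 genes (76.4%) under 1.5-fold. Large changes lay mainly on the negative side: among called genes with a change of at least 2-fold, 123 were positive and 576 negative. Of these 699 genes 650 lay below the median level, and at or above it the split was 16 positive to 33 negative, a ratio of 2.06 against 4.68 over all levels. The negative share over all levels was 82.4% (exact binomial 95% interval 79.4% to 85.2%, counting error only). The split of all called genes depended on the centring. With the fold changes re-centred on the median ribosomal protein gene and the test recomputed, 65.2% of the called genes were positive, against 43.9% as deposited.

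Among genes at or above the median level of 23.5 CPM, the largest positive changes in the authors' deposited table were in E2F7 (3.05-fold), an E2F repressor, and RRM2 (2.35-fold), the small subunit of ribonucleotide reductase. The cystine transporter SLC7A11 followed at 2.31-fold, the p53 relative TP73 at 2.29-fold and the tight junction gene CLDN1 at 2.23-fold. EZH2, the Polycomb methyltransferase, differed by 2.13-fold, the kinase gene HUNK by 2.14-fold, and E2F8, another E2F repressor, by 2.08-fold. The largest negative changes reached further. APOE, which encodes a lipid-carrying apolipoprotein, had a log2 fold change of -4.11 and the matricellular protein gene SPARC one of -3.47. PPP2R2B, CCDC80, LAMA2, OLFM3, EGLN3 and IGFBP5 followed between -1.75 and -1.47. The adjusted p of APOE and of SPARC is listed at 0 in the authors' deposited table, and those of the other 14 genes were at most 2.32e-39.

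**Figure D1:**
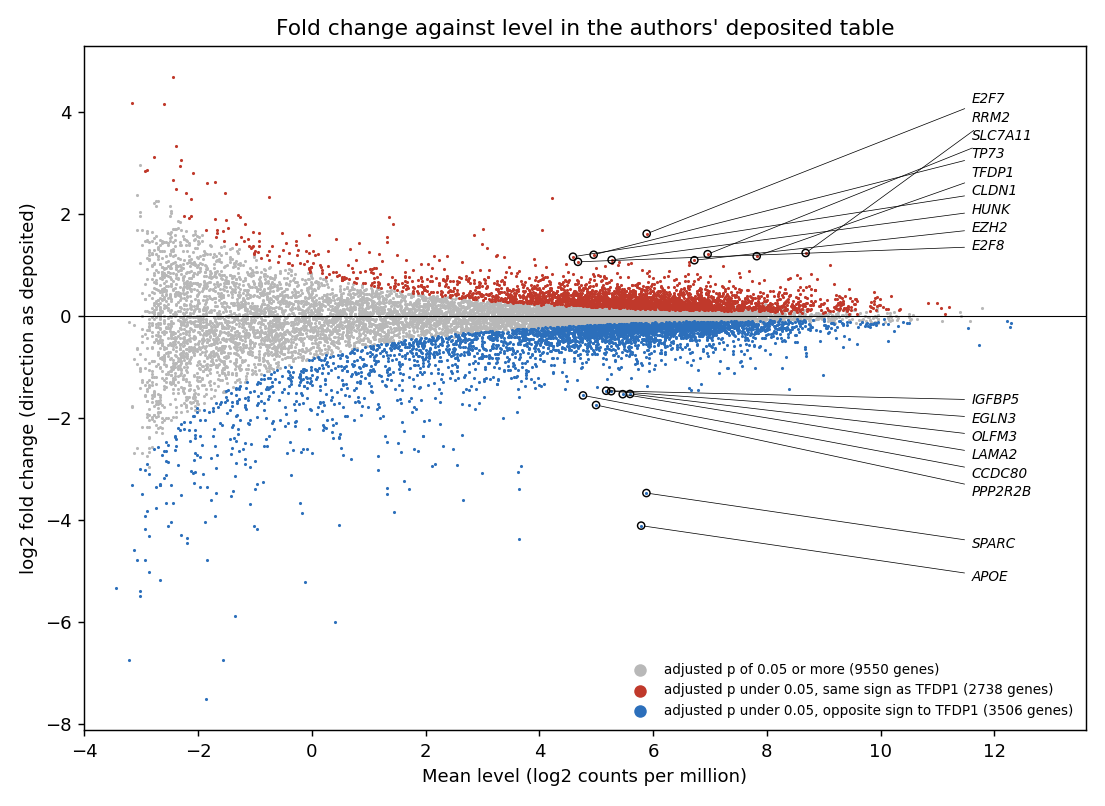
The log2 fold change of each of the 15794 genes in the authors' deposited table (y axis, direction as deposited) is plotted against its mean level in log2 CPM (x axis), with 2738 positive called genes in red, 3506 negative called genes in blue and 9550 genes that were not called in grey. TFDP1 and the 8 genes with the largest change on each side at or above the median level are circled and named, and APOE and SPARC lie far below the rest of the named genes.

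The list of E2F, DP and RB genes and their MuvB, MYB and FOXM1 partners gave 10 positive, 3 negative and 6 uncalled genes of 19 besides TFDP1, with a median log2 fold change of 0.23. The 12 E2F, DP and RB members themselves differed in sign, with 5 positive, 3 negative and 4 not called, and the 7 partners gave 5 positive and 0 negative. The atypical repressors E2F7 and E2F8 had log2 fold changes of 1.61 and 1.06 in the authors' deposited table, RB1 one of 0.54, the related pocket protein RBL1 0.47 and FOXM1, a driver of mitotic genes, 0.35. E2F2 was positive at 0.29, whereas E2F5 (-0.31), E2F6 (-0.34) and the TFDP1 paralogue TFDP2 (-0.29) were negative. E2F1 (0.01, adjusted p = 0.885), E2F3 (0.08), E2F4 (0.01) and RBL2 (0.06) did not pass the authors' test. Regulators of the G1/S transition gave 14 positive, 6 negative and 5 uncalled genes of 25, with a median of 0.24. This list mixes drivers and inhibitors of the transition, and called members of both kinds lay on either side. Its shift is therefore not a measure of G1/S activity. The E-type cyclins went opposite ways: CCNE2 had a log2 fold change of 2.30 (4.94-fold) and CCNE1 one of -0.28. FBXO5, an inhibitor of the anaphase-promoting complex, was at 0.87 and CDK2 at 0.60, all in the authors' deposited table. Both lists were shifted to the positive side against all other genes in limma's cameraPR, a competitive test of a list against other genes, with adjusted p of 1.42e-06 and 5.06e-06. With log2 fold changes as the statistic the G1/S list did not pass (adjusted p = 0.0751), and under the other alternatives its adjusted p was at most 0.0105. With p adjusted over the list alone, the E2F list had 10 positive and 3 negative genes and the G1/S list 15 and 7.

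The machinery of DNA replication, nucleotide supply, repair and mitosis was positive as a group. Of 48 replication genes 31 were positive, 4 negative and 13 not called, with a median log2 fold change of 0.19. Among them were the polymerase subunits POLD3 (1.05) and POLA1 (0.69), the helicase subunit MCM4 (0.50) and the sliding clamp PCNA (0.39) in the authors' deposited table. Of 26 nucleotide synthesis genes 16 were positive and 2 negative, led by RRM2 (1.23), RRM1 (0.64) and thymidylate synthase TYMS (0.69). DNA repair genes gave 21 positive and 2 negative of 31, with USP1 at 0.84, FANCI at 0.77 and EXO1 at 0.59. Genes of G2 and mitosis gave 30 positive, 0 negative and 6 uncalled of 36, with a median of 0.29. TOP2A was at 0.62, NUSAP1 at 0.77 and KIF11 at 0.67 in the authors' deposited table. Adjusted p from limma's cameraPR was 8.38e-09 for replication, 9.11e-07 for nucleotide synthesis, 8.38e-09 for repair and 5.62e-21 for mitosis. By Fisher's exact test, 83.3% of the mitotic genes were called positive against 17.2% of other genes (adjusted p = 4.19e-16). With p adjusted over the list alone, replication had 34 positive and 4 negative genes, nucleotide synthesis 16 and 2, repair 22 and 2, and mitosis 33 and 0.

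Of 70 replication-dependent histone genes listed, 35 were in the authors' deposited table, and 7 of these were negative, 28 not called and 0 positive. Their median log2 fold change was -0.56 as deposited and -0.36 with trends on transcript length and GC content removed. As deposited, HIST1H1C was at -1.37, HIST1H2BD at -1.36, HIST1H2BK at -0.81 and HIST3H2A at -1.03. The list did not pass limma's cameraPR (adjusted p = 0.118), but it did on the negative side with log2 fold changes as the statistic (adjusted p = 4.87e-04), with ranks (0.0238) and re-centred on the ribosomal protein median (0.0109). By Fisher's exact test its negative calls were not more frequent than the 22.2% of other genes (adjusted p = 1), while its positive calls, 0 of 35, were rarer than the 17.4% of other genes (adjusted p = 0.00801). Those other genes span all levels, and scarce genes were called less often. Below the median level 732 genes were called positive and 1416 negative, against 2006 and 2090 at or above it. Of the random lists matched in level, 0.52% had a lower median than the histone list, a ranking that ignores correlation between genes. The transcripts of the histone list mostly lack a poly(A) tail and were scarce after poly(A) selection, with a median level of 0.465 CPM. Their near-identical copies can share reads, so their values are uncertain. Histone chaperone and supply genes gave 16 positive and 4 negative of 28 (adjusted p = 6.31e-06 in limma's cameraPR), including the chaperone gene ASF1B (0.77), SLBP (0.54), whose product binds the histone mRNA stem-loop, and SSRP1 (0.34). Histone variants, whose transcripts are polyadenylated, gave 7 positive and 1 negative of 10 (adjusted p = 0.00108), with H2AFV at 0.51, H1FX at 0.37 and H2AFZ at 0.39. DNA methylation and Polycomb genes gave 12 positive and 3 negative of 21 (adjusted p = 0.00103). EZH2 was at 1.09 and UHRF1 at 0.51, but the demethylase gene KDM6B was at -0.67 in the authors' deposited table. Chromatin remodellers gave 14 positive and 3 negative of 25 (adjusted p = 0.00108), with BAZ1B at 0.45, PBRM1 at 0.44 and SMARCA2 at -0.61. With the same trends removed, the remodellers did not pass (adjusted p = 0.0882), although their median went only from 0.13 to 0.12. With log2 fold changes as the statistic the lists of histone variants (adjusted p = 0.321), DNA methylation and Polycomb (0.161) and remodellers (0.161) did not pass. With p adjusted over the list alone, the positive and negative counts were 0 and 7 for the replication-dependent histones, 18 and 4 for supply, 7 and 1 for variants, 12 and 3 for DNA methylation and Polycomb, and 17 and 3 for remodellers.

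Of 20 genes listed for the integrated stress response, the programme run by ATF4, 12 were positive and 5 negative, with a median log2 fold change of 0.33 (adjusted p = 2.52e-06 in limma's cameraPR). The list also holds genes of the unfolded protein response, and its members ranged from -0.77 to 1.21. SLC7A11 (1.21), asparagine synthetase ASNS (0.88) and the serine synthesis enzyme PHGDH (0.51) had the smallest p of the list in the authors' deposited table. Of 24 p53 targets, 9 were negative, 1 positive and 14 not called. The pro-apoptotic BBC3 was at -0.76, GDF15 at -1.22 and TP53I3 at -0.70, and the list did not pass limma's cameraPR (adjusted p = 0.0651) except with a preset correlation of 0 (0.0382). Apoptosis genes went both ways, with 5 positive and 6 negative of 21 (adjusted p = 0.572). Their median was 0.01, or -0.04 with length and GC trends removed, and their mean -0.0027, and TP73 (1.20), BCL2L1 (-0.55) and BMF (-1.05) had the smallest p. Interferon-stimulated genes gave 9 negative and 1 positive of 23 and a median of -0.18 (adjusted p = 0.0573), with BST2 at -0.55, OAS2 at -1.61 and IFITM1 at -2.38, the latter at a level of 1.40 CPM. That list passed under 4 of the alternatives, with adjusted p from 0.0232 to 0.0461. Of 15 heat shock genes 4 were negative and 0 positive (adjusted p = 0.237), among them HSPB1 at -0.64, HSPA4 at -0.27 and BAG3 at -0.21. With p adjusted over the list alone, the positive and negative counts were 14 and 5 for the integrated stress response, 2 and 9 for p53 targets, 5 and 6 for apoptosis, 2 and 9 for interferon and 0 and 4 for heat shock.

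Genes of energy metabolism and translation leaned to the negative side by small amounts. Glycolysis and hypoxia genes gave 13 negative and 2 positive of 25, with a median log2 fold change of -0.12 (adjusted p = 0.00172 in limma's cameraPR). With length and GC trends removed the median was -0.05 (adjusted p = 0.0466), and with log2 fold changes as the statistic the list did not pass (0.412). EGLN3, a prolyl hydroxylase induced by hypoxia, was at -1.48, hexokinase HK1 at -0.44 and the glucose transporter SLC2A3 was negative by 2.82-fold in the authors' deposited table. Oxidative phosphorylation genes gave 17 negative and 1 positive of 31, with a median of -0.14 (adjusted p = 0.0135), and NDUFV1 was at -0.36, COX6B1 at -0.33 and CYC1 at -0.22. Of 77 ribosomal protein genes 26 were negative, 51 not called and 0 positive, with a median of -0.10 (adjusted p = 0.0392). RPS27A was at -0.23, and RPS10 was at -0.65 with a level of 11.2 CPM, a value that is uncertain because the gene overlaps a read-through gene. Both of these calls were lost with a preset correlation of 0.05, at an adjusted p of 0.0935 for oxidative phosphorylation and 0.242 for ribosomal proteins, with log2 fold changes as the statistic (adjusted p = 0.856 and 0.964) and with the length and GC trends removed (0.169 and 0.694). Removing the trends took the ribosomal median from -0.10 to -0.03 and that of oxidative phosphorylation from -0.14 over all members to -0.13 over the 27 with an annotated transcript. The ribosomal call also ended among genes at or above the median level (adjusted p = 0.0520) and with re-centring on the median gene (0.0733). Of 24 cholesterol synthesis genes 5 were negative and 1 positive (adjusted p = 0.572), with TM7SF2 at -0.85, MVK at -0.29 and NSDHL at -0.16. With p adjusted over the list alone, the positive and negative counts were 2 and 13 for glycolysis and hypoxia, 1 and 19 for oxidative phosphorylation, 0 and 31 for ribosomal proteins and 1 and 5 for cholesterol synthesis.

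Fibroblast and epithelial markers were negative as groups, and blood markers did not pass the list test. Of 11 fibroblast and mesenchymal markers 7 were negative and 1 positive, with a median log2 fold change of -0.30 (adjusted p = 2.16e-06 in limma's cameraPR). SPARC was at -3.47, THY1 at -2.66 and the matrix protein gene POSTN at -2.00 in the authors' deposited table, the last at 2.30 CPM. Of 9 epithelial markers 5 were negative and 0 positive, with a median of -0.69 (adjusted p = 2.26e-04). Their negative calls did not pass Fisher's exact test (adjusted p = 0.0731), and their median level was only 2.36 CPM. The keratin genes KRT8 and KRT18 were at -2.94 and -0.52, and the adhesion gene EPCAM was at -4.18 with a level of 0.515 CPM, so that few reads lay behind its fold change. Of 13 neuronal markers 4 were negative and 3 positive. The list did not pass (adjusted p = 0.228), but did on the negative side among genes at or above the median level (4.66e-04), where only 3 of the 13 were left, and with log2 fold changes as the statistic (0.00792). The mean log2 fold change of the list was -0.64, with the lowest member at -6.74, against a median of -0.15. The tubulin gene TUBB3 (-1.13) and NES (-0.90) stood against the synaptic vesicle gene SYP (1.71). Only 5 of 22 blood markers were in the table. The receptor gene KIT (-0.98) was negative, the integrin gene ITGA2B (0.49) positive and 3 were not called, among them CD34 with an adjusted p of 0.294 (list adjusted p = 0.572). With p adjusted over the list alone, the positive and negative counts were 1 and 7 for fibroblast, 0 and 5 for epithelial, 3 and 4 for neuronal and 1 and 1 for blood markers.

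The neighbours of TFDP1 in chromosome band 13q34 did not share its change. Of 16 tested, 12 were not called, 3 were negative and 1 was positive, and the counts were 1 positive and 3 negative with p adjusted over the list alone. CHAMP1 was at 0.38 and LAMP1 at -0.15 in the authors' deposited table. GRK1 was also negative, at -6.74 with an adjusted p of 4.18e-07 in the authors' deposited table. Its level was only 0.338 CPM, so few reads lay behind its fold change and the size of that change is uncertain. The median of the neighbours was -0.03 and their mean -0.41, set by GRK1, while the direction in limma's cameraPR was positive with an adjusted p of 0.962. In all, 16 of the 25 lists passed limma's cameraPR, 11 on the positive and 5 on the negative side.

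**Figure D2:**
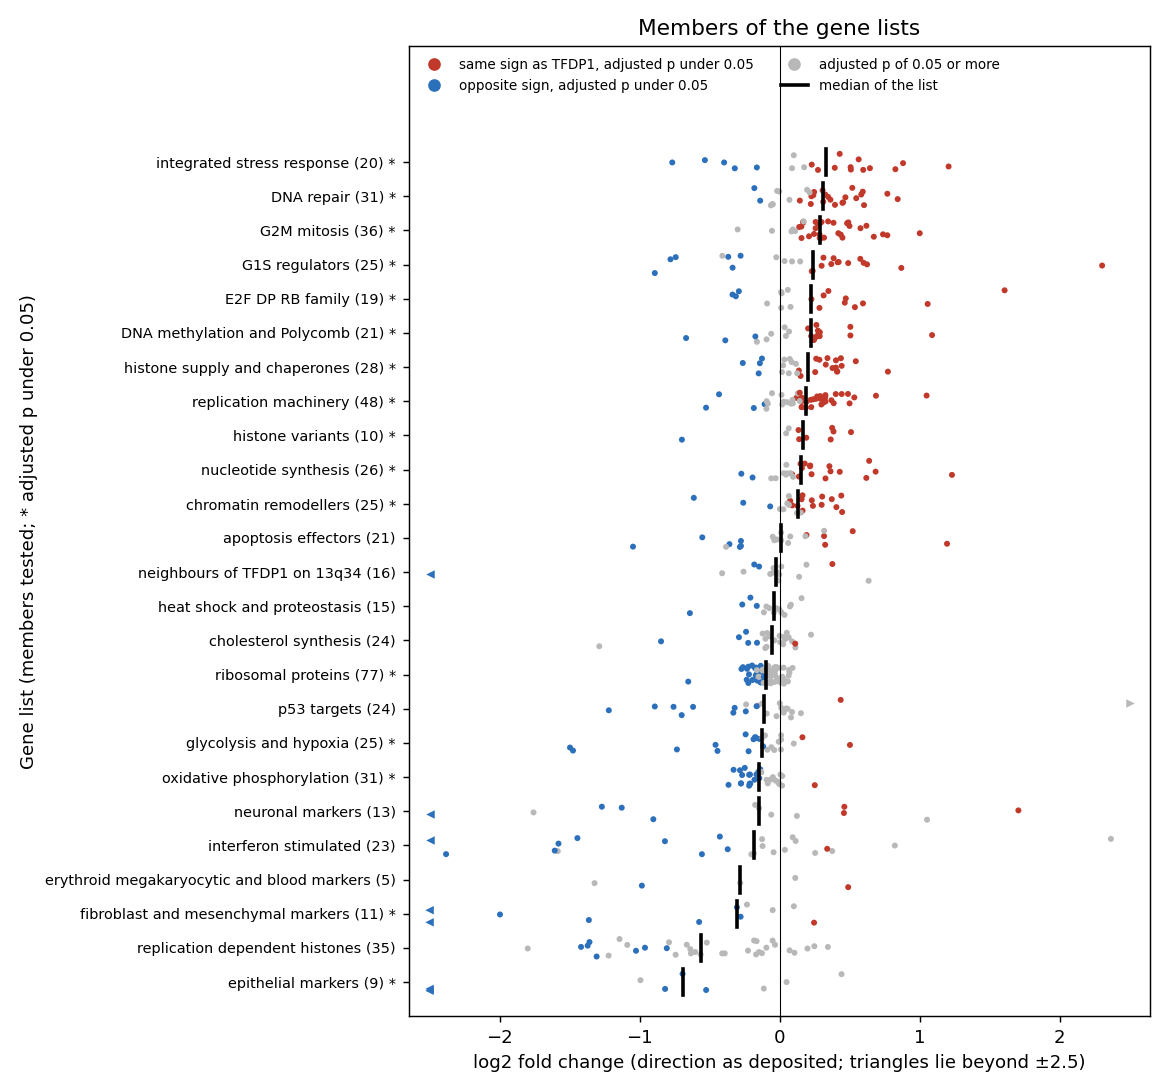
Each point is a member of 1 of the 25 gene lists, placed by its log2 fold change in the authors' deposited table (x axis, direction as deposited) and coloured red or blue where it was called positive or negative and grey where it was not, with a black bar at the median of each list and triangles for the 8 members beyond 2.5 on either side. The lists of stress response, repair, mitosis, replication and chromatin genes lie to the right of 0, with medians from 0.13 to 0.33. The epithelial, replication-dependent histone and mesenchymal lists lie to the left, with medians of -0.69, -0.56 and -0.30.

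The fold changes followed the base composition of the transcripts. Across the 14777 genes with an annotated transcript, Spearman's rho between log2 fold change and transcript GC content was -0.27, and it was -0.37 at or above the median level (genes are not independent replicates). With the genes split into 5 bins of nearly equal size by GC content, the lowest bin reached up to 41.1% GC. There the median log2 fold change was 0.10 and 914 genes were called positive against 316 negative. In the highest bin, from 58.6% GC, the median was -0.16, with 240 positive and 1070 negative. With the trends on transcript length and GC content removed, 5672 genes were called, 47.3% of them positive, and 13 lists passed limma's cameraPR. The E2F list and the lists of G1/S, replication, nucleotide synthesis, mitosis and repair were among them, with adjusted p of at most 2.03e-06. Chromosomes differed as well: 11 of 23 passed Fisher's exact test and 10 a permutation test of the medians. The median gene of chromosome 13 lay 0.12 above all other genes (adjusted p = 1.52e-07 in Fisher's exact test), that of chromosome 18 lay 0.10 above (adjusted p = 0.0191), and that of chromosome 19 lay at -0.10 relative to them (adjusted p = 3.28e-11). Median transcript GC content was 42.8% on chromosome 13 and 59.0% on chromosome 19. Chromosome X did not follow this order: at 46.5% GC it lay at -0.043 (adjusted p = 0.0243), whereas chromosome 2, at 45.6%, lay 0.032 above. With the trends removed no chromosome passed. The smallest adjusted p was 0.0729, on chromosomes 13 and X. The difference was then 0.043 on chromosome 13 (bootstrap 95% interval 0.0086 to 0.088) and -0.042 on X (-0.076 to -0.018), and for the other 9 chromosomes that had passed the interval took in 0.

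**Figure D3:**
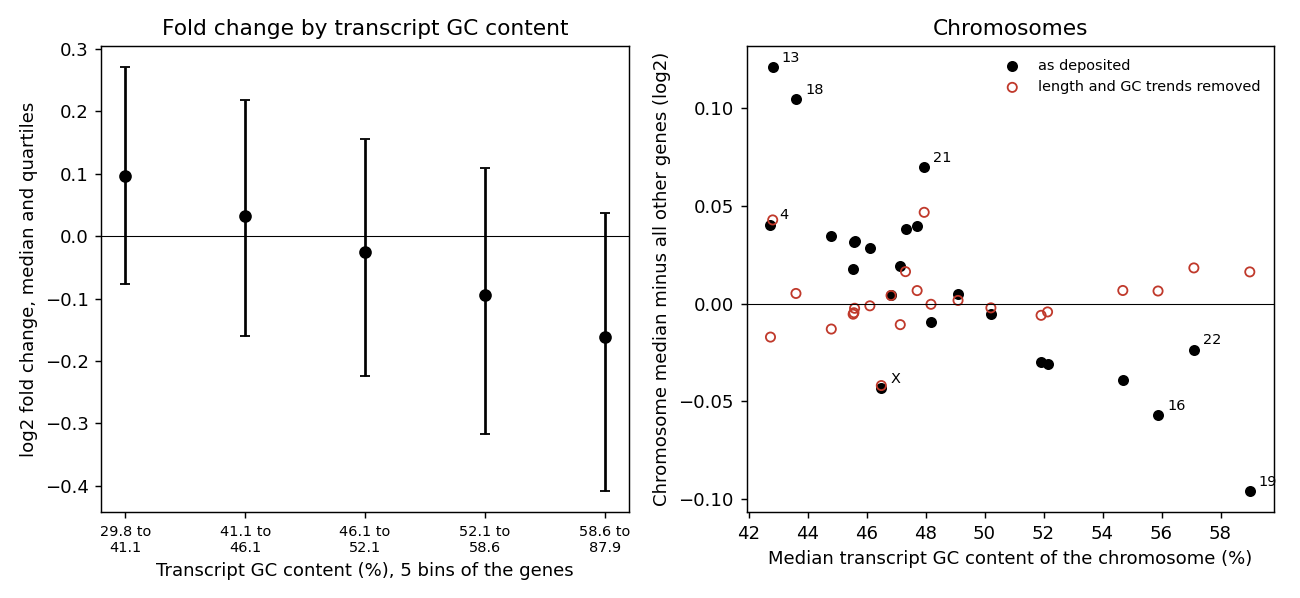
The left panel gives the median and quartiles of the log2 fold change (y axis, direction as deposited) in 5 bins of the genes by transcript GC content in percent (x axis), with medians from 0.10 in the lowest bin to -0.16 in the highest. The right panel places each of 23 chromosomes by the median GC content of its transcripts in percent (x axis) and by its median log2 fold change minus that of all other genes (y axis), as deposited in black and with length and GC trends removed in red, where chromosome 13 goes from 0.12 to 0.04 and chromosome X stays at -0.04.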

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

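The alternatives that recompute the test of single genes after re-centring, re-centre the list test on the ribosomal protein median, remove length and GC trends or leave out genes with extreme likelihood ratios were chosen after the data were seen, and the others before. Against 6244 called genes, 4816 of the 15794 passed at an adjusted p of 0.01 and 7122 at 0.1, 6424 with the adjustment over the rows analysed and 6454 with the test re-centred on the median gene. The count was 699 (123 positive, 576 negative) with a change of at least 2-fold, 4096 (2090 negative) at or above the median level and 2464 (1030 positive, 1434 negative) with Bonferroni adjustment. These are stricter by construction. With the test re-centred on the ribosomal protein median, 4493 genes were positive, against 2738, and the cause was not tested. With length and GC trends removed, fewer genes could be tested and 5672 were called. Between 12 and 18 of the 25 lists passed under the alternatives, against 16. For single lists, 192 results kept their direction and side of the threshold, 16 lost the call and 10 gained it. The gains were those of the replication-dependent histones (3, with adjusted p from 4.87e-04 to 0.0238), interferon (4, from 0.0232 to 0.0461), neuronal markers (2, 4.66e-04 and 0.00792) and p53 targets (1, 0.0382). The losses included ribosomal proteins under 6 alternatives (adjusted p from 0.0520 to 0.964) and oxidative phosphorylation under 4 (0.0935 to 0.856). For ribosomal proteins, 1 of the 6 was re-centring on their own median (0.383), where the loss was built in. With log2 fold changes as the statistic the direction of 3 lists that had not passed was reversed: p53 targets (adjusted p = 0.964), heat shock (0.964) and the TFDP1 neighbours (0.0851), the last also with ranks (0.895). The cause was not tested. G1/S regulators, histone variants, DNA methylation and Polycomb, remodellers, glycolysis and hypoxia, ribosomal proteins and oxidative phosphorylation lost their calls with that statistic, which gives scarce genes more weight. Of the Fisher tests of lists among called genes, 17 passed, and 2 did with calls of at least 2-fold, where few members remain. TFDP1 was at 1.26 when re-centred on the ribosomal protein median. No paired analysis was possible because values per sample were not used here. For the same reason leaving out replicates, other splits of the samples, spike-in scaling, DESeq2, other pseudocounts, no filter on low counts and estimated correlations were not run. Depth limits the scarce genes most, with a median approximate standard error of 0.89 between -3 and -2 log2 CPM.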

Other observations

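The tests on the sign of TFDP1, on extreme likelihood ratios and on the GC explanation of the chromosome shifts were chosen after the results they concern were seen, as were the use of the corrected shift to judge copy number and the gene groups in the next paragraph.

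Groups of genes that share the root of their symbol gave patterns beyond the fixed lists. Of 190 roots tested with limma's cameraPR, 6 passed, 5 on the positive and 1 on the negative side. Collagen genes (root COL) were the negative group, with 17 negative and 0 positive of 30 and a median log2 fold change of -0.37 in the authors' deposited table (adjusted p = 1.21e-05). Splicing factors of the SR family (SRSF) gave 7 positive and 0 negative of 12 (adjusted p = 1.48e-05), and RAD genes 12 and 0 of 20 (adjusted p = 2.80e-04). MCM genes gave 8 and 1 of 12 (adjusted p = 0.0107), but most members of that group are on the replication list already. Kinesins (KIF) gave 16 positive and 6 negative of 38 and centrosomal CEP genes 15 and 1 of 37, but neither passed with length and GC trends removed (adjusted p = 0.192 and 0.462), whereas the other 4 did. With ranks the SRSF group (adjusted p = 0.0800), whose member SRSF1 is among the genes with extreme likelihood ratios described last, and the kinesins (adjusted p = 0.247) did not pass.

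The positive sign of TFDP1 is open to opposite readings. If the fold change were control over knockout, the transcript would be lower in the knockout, and genes that E2F activates would share its sign. The medians of the replication, nucleotide synthesis and repair lists were positive, the lowest at 0.15, which that reading requires. A knockout that raises both its own transcript and these genes predicts the same medians, so the readings cannot be told apart from this table. The negative median of the replication-dependent histones, a list whose call depends on the statistic and the centring, does not settle it.

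Called genes with changes of at least 2-fold were 4.68 times as often negative as positive. Removing length and GC trends took the ratio from 4.77 to 4.09 (95% interval 3.35 to 5.03). The removal shifts only the centre of the fold changes, whose medians ran from 0.10 to -0.16 over the GC bins. At a 2-fold cut the ratio could therefore hardly change, and the result argues only against a shift of the centre of that size. A spread of fold changes that widens with GC content was not removed and stays open. Re-centring on the median gene left the ratio at 4.29 (3.54 to 5.24), but that median was only -0.025, so the ratio could hardly change here either. The result argues only against an offset of that size, and a larger offset in scaling was not tested. Low counts remain open, because at or above the median level only 16 positive and 33 negative genes were left, a ratio of 2.06, with a negative share of 67.3% (exact binomial 95% interval 52.5% to 80.1%) that still takes in a ratio of 1.5. An effect of TFDP1 loss stays open too, as no biological explanation was tested.

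Chromosome 13, which carries TFDP1, was shifted by 0.12 against all other genes, chromosome 18 by 0.10 and chromosome X by -0.043, and a copy number difference between the groups was considered beforehand as a source. By the test set beforehand, a shift above 0.1 as deposited with an adjusted permutation p under 0.05, it would have been accepted for chromosomes 13 and 18 (adjusted permutation p = 7.67e-04 for both, from the smallest p that 10000 permutations can give, 0.0001). With length and GC trends removed, the shifts were 0.043 on chromosome 13 (bootstrap 95% interval 0.0086 to 0.088), 0.0052 on 18 (-0.023 to 0.057) and -0.042 on X (-0.076 to -0.018), which argues against a copy number difference large enough for 0.1 on these chromosomes, though a smaller one stays open. The same intervals, which are not adjusted over chromosomes, argue against GC content or length as the source of the shift of X, which the removal left in place, and as the whole source on chromosome 13, where it shrank from 0.12 (interval 0.073 to 0.15) but not to 0. Neither passed Fisher's exact test after the removal (adjusted p = 0.0729 for both). Fewer other chromosomes then had a small p, which made the adjustment stricter for X but not for chromosome 13. The unadjusted p went from 1.32e-08 to 0.0063 on chromosome 13, whose shift shrank, and from 0.0092 to 0.0032 on X. What shifted X is open. On the other 9 chromosomes that had passed, a group formed after these values were seen, the intervals after removal took in 0 and no longer the shift before, and the largest shift left was -0.017, on chromosome 4, as a dependence on GC content or length would predict. What produces that dependence is open: a difference in library preparation between the groups and a response of AT-rich genes to TFDP1 loss may each give it, and no value per library was used that would separate them.

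Among 1859 genes of at least 128 CPM, 34 had likelihood ratios above the counting limit set by scarce genes, which corresponds to about 35400000 reads per group. The translation factor gene EEF2, with a likelihood ratio of 132751 at a log2 fold change of -0.09 in the authors' deposited table, would need 371 times that depth, so deep sequencing does not account for it. The other genes ranged from 65 times (EIF4G2) down to 1.11 times (AMD1), so that conclusion does not extend to all 34. Of the 34 genes 33 were called, and 6 of the 9 genes whose p is listed at 0 are among them.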
